A study of Mus musculus with 6 samples.

How the data were processed

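Gene expression was measured by RNA sequencing in 6 libraries of cultured lung endothelial cells from Ch25h-null mice. Per the labels' protocols, RNA was taken with Trizol, polyA libraries were made with a TruSeq kit, and 75 bp single-end reads were sequenced on a NextSeq 500. The strand of the libraries is not given in the sources used here, so reads of overlapping or antisense genes are not told apart. Per the submitters' processing notes, reads were quantified with kallisto 0.45.0 and processed in R 4.0.0 with edgeR and limma. The authors deposited a raw table and a filtered, normalized table, and both hold estimated counts per gene symbol, of which 61.2% are not whole numbers. The filtered table holds 13098 genes with the same estimated counts as the raw table in every value, so the deposited values carry no normalization. Its genes are those with more than 1 CPM in at least 2 libraries, with 0 disagreements. Only the estimated counts of the raw table were used in the main tests. The submitters' notes name the human build GRCh38, whereas the symbols are those of mouse genes, so no coordinates are given here.

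The groups were vehicle, TEV, and TEV plus reserpine, with 2 libraries each, as the sample labels state. The series text can also be read as reserpine pretreatment of all cells; the sample labels say otherwise and were followed. The replicate numbers in the text are those of the sample titles, and the descriptions number the libraries of both vesicle groups 2 and 3. All 6 columns were mapped to a sample.

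The raw table held 30055 symbols, of which 8192 had no count in any library, and 28229 matched a mouse GENCODE symbol. Estimated counts were rounded, filtered with edgeR's filterByExpr to 15035 genes and scaled with TMM factors between 0.941 and 1.04. Means and SDs of CPM and CPM of single libraries in the text were computed here from the rounded, filtered counts with TMM-scaled library sizes. The CPM of Ch25h, of a count of 3 and of the filters used library totals without TMM factors. Each comparison (TEV against vehicle, TEV plus reserpine against TEV, and TEV plus reserpine against vehicle) was a contrast in 1 edgeR quasi-likelihood model of all 6 libraries, with 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

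Total depth ranged from 22270657 to 81225627 estimated counts, and the most abundant gene held 1.46% to 1.84% of a library. For a gene with no count in a group, the change is given as a lower bound against 3 counts over the group. For a gene with 1 to 3 counts it is given as a ratio with a 95% counting interval. No fitted log2 change is printed for either.

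The 33 gene lists were fixed before the files were opened and tested with limma's camera on voom values, with a preset inter-gene correlation of 0.01. The lists were angiogenesis and tip cells, endothelial identity, endothelial activation and adhesion, type I interferon response, interferon receptor and signalling, antigen presentation, cholesterol biosynthesis, LXR targets, cell cycle, hypoxia and glycolysis, and the unfolded protein response. Further lists were the integrated stress and amino acid response, heat shock, NRF2, p53 targets, TGF-beta response and matrix, endothelial to mesenchymal transition, immediate early genes, lysosome, endocytosis, immune checkpoint, oxysterol enzymes, monoamine genes, drug response and oxidative phosphorylation. The last were markers of fibroblasts, pericytes and smooth muscle, macrophages and leukocytes, lung epithelium and mesothelium, lymphatic endothelium and colon tumour epithelium, mitochondrially encoded transcripts, and ribosomal protein genes. The TGF-beta list shares Col1a1, Col1a2 and Col3a1 with the fibroblast list, and the mesenchymal transition list shares Acta2, Tagln and Cnn1 with the pericyte list. Camera was also run with the correlation estimated for each list. Genes with near-identical copies, members of multigene families and mitochondrial genes with nuclear copies can share reads.

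Genes named in the text follow a rule fixed beforehand. Named in each comparison were the 10 largest and 10 smallest log2 changes among called genes with a mean of at least 5 CPM, together with Ch25h. Slc18a2 lies outside the rule and was added after its values were seen. The rule also permitted up to 4 called and 2 uncalled members of each list, of which some were named; a few single-gene results are not reported here. Which of these permitted list members were named was chosen after their values were seen, and uncalled members whose sign changed between settings were left unnamed. The rule permitted 604 values, 420 called and 184 uncalled. No setting changed the sign of a called value, and the sign of between 0 and 21 of the uncalled values changed in a setting. Between 0 and 44 of the 420 calls were lost in a setting, the most with the block from the description numbers. Leaving out TEV replicate 1, or replicate 1 or 2 of TEV plus reserpine, lost 32, 33 and 31 calls.

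The test was checked on simulated data with the depth and spread of these libraries. Of 100 genes changed by 1 on the log2 scale, 67, 59 and 54 were recovered in the 3 comparisons, and of 100 changed by 2, 83, 83 and 76 were recovered. Among the unchanged genes, 20, 15 and 16 were called. Set beside the recovered genes of both sizes, these false calls were a larger share of all calls than the adjusted p threshold aims at. The threshold was therefore liberal in this check, in each comparison. A shifted list was recovered, and 0 of 20 unshifted lists were called. Opposite and same-direction calls of comparisons that share libraries were set beside 20 simulations of unchanged groups. They were also counted with a different TEV library in each comparison, in an edgeR model with 2 residual degrees of freedom that took the lone libraries to vary like the other groups.

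Alternatives were DESeq2 size factors, scaling by library size alone, the DESeq2 Wald test, limma-voom, no filter, a filter of 5 CPM in 2 libraries, only the 2 groups compared, and the replicate number as a block. Others were a minimum log2 change of 1, each library left out in turn, limma-trend on log CPM of the filtered table, and fry in place of camera. Thinning to the smallest library and removal of genes far lower in both vesicle groups were added after the data were seen. The lists of arterial, venous and junction genes and of further markers of other cell types were also chosen after the data were seen.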

Results

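RNA was sequenced from lung endothelial cells of Ch25h-null C57BL6 mice, which were 3 weeks old and labelled female. Ch25h encodes cholesterol 25-hydroxylase, the enzyme that makes 25-hydroxycholesterol. The cultured cells received vehicle, tumour-derived extracellular vesicles (TEV), or TEV after reserpine, a blocker of vesicular monoamine transporters used against hypertension. The vesicles came from MC38 mouse colorectal tumour cells and were given at 20 µg per ml for 12 h. Reserpine was added at 10 µM for 8 h before the vesicles. Each of the 3 groups held 2 libraries. Total estimated counts were 41528816 and 27528493 for vehicle, 38305039 and 81225627 for TEV, and 22270657 and 34511418 for TEV plus reserpine. A count of 3 corresponded to between 0.0369 and 0.135 counts scaled to library size (CPM) in these libraries. Counting intervals and floors given with fold changes below cover counting error only.

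Ch25h reads were few in every library. They came to 15.2 and 9.09 estimated counts (0.365 and 0.330 CPM) with vehicle, and to 11.9 and 40.8 (0.311 and 0.502 CPM) with TEV. With TEV plus reserpine they came to 23.8 and 31.7 (1.07 and 0.918 CPM). Which part of the gene was deleted is not given in the sources used here, so these reads can lie outside it and do not check the genotype. By edgeR, Ch25h was not called in TEV against vehicle (log2 change 0.39, adjusted p = 0.509) or in TEV plus reserpine against TEV (1.18, adjusted p = 0.0797). It was called higher in TEV plus reserpine against vehicle (1.57, adjusted p = 0.0334). That call ended when vehicle replicate 1 (edgeR adjusted p = 0.138), vehicle replicate 2 (0.148), TEV replicate 2 (0.0504), or replicate 1 (0.125) or 2 (0.0920) of TEV plus reserpine was left out, and with DESeq2 (0.0837) or libraries thinned to the smallest (0.0564).

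The groups separated on the first principal components of log2 CPM. The first component held 61.7% of the variance and set both vesicle groups apart from vehicle. The second held 22.9% and set TEV plus reserpine apart from TEV. Replicates of a group differed by more than sampling noise, with a mean chi-square per gene of 19.5 for vehicle, 43.4 for TEV and 20.6 for TEV plus reserpine (genes with a pooled count of at least 50). The sources used here do not say whether the replicates were separate cultures or animals, so every p-value below measures the spread between these libraries alone.

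**Figure D1:**
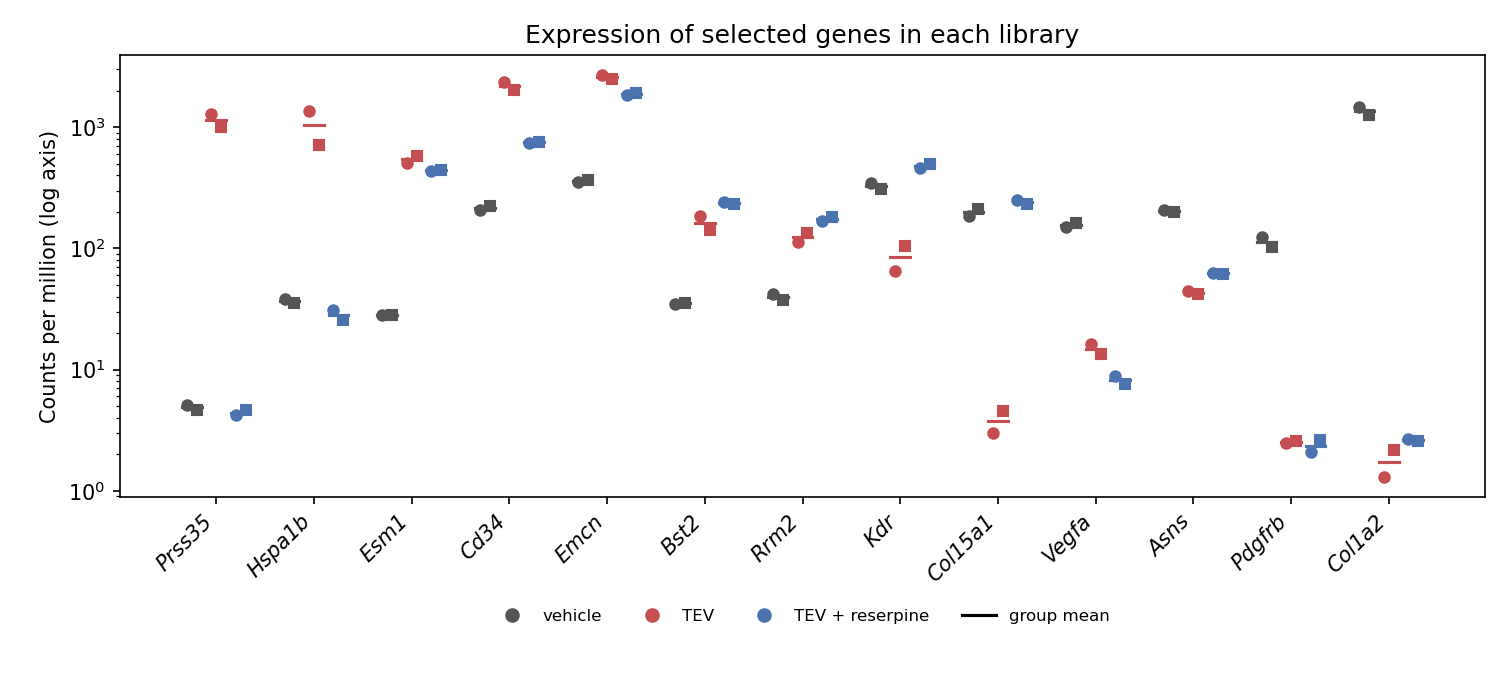
CPM (log axis) of 13 genes in the 6 libraries; circles are replicate 1, squares are replicate 2 and bars are the means of the 2 libraries of each group. Prss35 averaged 1142 CPM with TEV, against 4.89 CPM with vehicle and 4.40 CPM with TEV plus reserpine, whereas Col1a2 was below 3 CPM in all 4 libraries that received vesicles.

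The first comparison asked what tumour vesicles change in endothelial cells that lack Ch25h. With TEV, all 35 cell cycle genes, 12 of 15 heat shock genes, 18 of 27 type I interferon response genes and 15 of 26 oxidative phosphorylation genes were called higher than with vehicle. Called lower were 14 of 23 amino acid response genes, 13 of 15 fibroblast markers and 11 of 13 pericyte markers. No list was called by limma camera with an estimated correlation (smallest adjusted p = 0.462 with an estimated correlation). Prss35, a serine protease family member, rose from 4.89 ± 0.313 to 1142 ± 194 CPM (SD, n = 2 each). Akr1b3, the aldose reductase gene, rose from 284 ± 9.82 to 14501 ± 2756 CPM (SD, n = 2 each). Col1a2, a collagen I chain, fell from 1358 ± 154 to 1.73 ± 0.608 CPM (SD, n = 2 each).

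Of 15035 genes tested, 3773 were higher and 3703 lower with TEV by edgeR's quasi-likelihood test at an adjusted p under 0.05. The change was at least 2-fold for 1346 and 2106 of them. Scaling by library size alone moved the median log2 change of all genes from 0.01 to -0.11 and the share of calls that were higher from 50.5% to 39.8%.

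Besides Prss35 (log2 change 7.86, edgeR adjusted p = 2.18e-06) and Akr1b3 (5.67, 3.4e-06), the 10 largest increases included Enpp2, which encodes autotaxin (5.69, 7.38e-06). They also included Tlr13, a sensor of bacterial ribosomal RNA (5.59, 1.35e-05), Pkd1l1 (5.86, 0.000207), Tal2 (6.68, 0.000341) and the cytokine gene Tslp (5.93, 0.00165). Gper1, an oestrogen-responsive receptor, averaged 78.5 ± 62.4 CPM (SD, n = 2) with TEV, with a log2 change of 7.03 (edgeR adjusted p = 0.000491). Grik1, a glutamate receptor subunit, had no counts with vehicle and was at least 473-fold higher with TEV, against a floor of 3 counts over the group. Eci1 (6.98, edgeR adjusted p = 0.0127) was no longer called without vehicle replicate 1 (adjusted p = 0.0605). Without vehicle replicate 2 no counts of Eci1 remained in vehicle, and without vehicle replicate 1 none of Tslp, so no change is given there.

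Among the 10 largest decreases, Cspg4, a proteoglycan of pericytes, had no counts with TEV and was at least 625-fold lower than with vehicle. Aplnr, the apelin receptor, fell by 10.32 on the log2 scale (edgeR adjusted p = 2.18e-06), and Mgp, the matrix Gla protein gene, fell by 10.21 (2.18e-06). Col1a2 fell by 9.53 (2.18e-06). Slc26a7 was 1100-fold lower, with a counting interval of 304 to 9090. The other log2 changes were those of Tspan11 (-9.36, edgeR adjusted p = 1.43e-05), the urea transporter Slc14a1 (-8.98, 2.18e-06), Aldh1a2, which makes retinoic acid (-8.79, 5.03e-05), Fmo2 (-8.71, 3.61e-06) and Kctd15 (-8.63, 6.56e-05).

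All 35 cell cycle genes were called higher with TEV, also when adjusted over the list alone, with a median log2 change of 1.19. Examples were the replication helicase genes Mcm3 (1.46) and Mcm6 (1.13) and the ribonucleotide reductase subunit Rrm2 (1.62). The list differed from other genes by limma's camera test (adjusted p = 1.03e-12, and adjusted p = 0.462 with an estimated correlation). Of 15 heat shock genes, 12 were higher and 1 lower (13 and 2 adjusted over the list alone). The chaperone Hspa1b, whose reads can be shared with its near-identical copy, rose from 36.5 ± 1.97 to 1034 ± 451 CPM (SD, n = 2 each), and Cryab rose by 3.56 and Hsph1 by 2.15 on the log2 scale. The list's camera test gave adjusted p = 0.000566 (adjusted p = 0.462 with an estimated correlation). Of 26 oxidative phosphorylation genes, 15 were higher and 2 lower (16 and 2 adjusted over the list alone), with Cox4i1 at 0.71 and Sdha at 0.71 on the log2 scale. The camera test of that list gave adjusted p = 0.00317 (adjusted p = 0.481 with an estimated correlation).

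Type I interferon response genes were higher with TEV for 18 of 27 and lower for 1 (21 and 1 adjusted over the list alone), with a median of 1.36. Bst2, which encodes the viral restriction factor tetherin, rose from 35.1 ± 0.670 to 163 ± 30.0 CPM (SD, n = 2 each), and Ddx58, an RNA sensor, rose by 1.11 on the log2 scale. Oas1a belongs to a multigene family and is uncertain for that reason (log2 change 3.67, edgeR adjusted p = 0.000682). The list's camera test gave adjusted p = 0.00181 (adjusted p = 0.683 with an estimated correlation), and with fry the list was not called (0.0838). Of 9 genes of the interferon receptor and its signalling, 4 were higher and 4 lower (the same counts adjusted over the list alone). Among them Ifnar1, a chain of the receptor, fell by 1.13 on the log2 scale (edgeR adjusted p = 0.000130) and the kinase Jak1 fell by 0.43 (0.00332). Of 14 antigen presentation genes, 6 were higher and 1 lower (the same adjusted over the list alone), among them H2-D1 (0.89) and Tapbp (1.54). Neither of these lists was called by camera (adjusted p = 0.671 and 0.0799).

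Integrated stress and amino acid response genes were lower for 14 of 23 and higher for 5 (the same adjusted over the list alone), with a median of -0.93. Asns, asparagine synthetase, fell from 202 ± 4.97 to 43.0 ± 1.67 CPM (SD, n = 2 each), the transcription factor Atf5 fell by 2.15 and the amino acid transporter Slc7a5 by 2.32 on the log2 scale. The camera test gave adjusted p = 0.00189 (adjusted p = 0.462 with an estimated correlation). Angiogenesis and tip cell genes moved both ways, with 7 of 30 higher and 17 lower (the same adjusted over the list alone). Esm1, a tip cell gene, rose by 4.27 and the vessel-destabilising ligand Angpt2 by 2.81, whereas the growth factor Vegfa fell by 3.41 on the log2 scale. The camera test of that list gave adjusted p = 0.0304 (adjusted p = 0.462 with an estimated correlation). Of 25 endothelial identity genes, 13 were higher and 8 lower (the same adjusted over the list alone), and the list was not called (camera adjusted p = 0.136). Cd34 rose by 3.35, Emcn by 2.84, Eng by 1.96 and Pecam1 by 1.42 on the log2 scale.

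Markers of other cell types fell in the libraries with TEV. Of 15 fibroblast markers, 13 were lower and 1 higher, of 13 pericyte and smooth muscle markers 11 were lower, and of 16 macrophage and leukocyte markers 8 were lower and 1 higher (the same counts adjusted over the list alone, for each). The medians were -4.27, -2.88 and -2.20, and the fibroblast median was -4.10 with genes of an empty group at their bound. Pdgfra fell from 151 ± 16.3 to 4.32 ± 0.572 CPM, Pdgfrb from 113 ± 14.2 to 2.53 ± 0.0425 CPM and Lyz2 from 26.8 ± 3.31 to 4.01 ± 1.20 CPM (SD, n = 2 each). The camera tests gave adjusted p = 7.5e-06, 7.83e-05 and 0.0307 (each adjusted p = 0.462 with an estimated correlation), and the macrophage call ended without TEV replicate 2 (adjusted p = 0.061). With these markers moved 2 lists that share genes with them. TGF-beta response and matrix genes were lower for 17 of 28 and higher for 5 (18 and 6 adjusted over the list alone), with Bgn at -2.90 and Lox at -3.05 on the log2 scale. Genes of endothelial to mesenchymal transition were lower for 10 of 17 and higher for 1 (12 and 2 adjusted over the list alone), with the smooth muscle actin gene Acta2 at -2.88 and the transcription factor Twist1 at -3.39. Their camera tests gave adjusted p = 0.00297 and 0.00419 (adjusted p = 0.504 and 0.462 with an estimated correlation).

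The other lists were not called by camera in this comparison, and several held members that moved in both directions. Sterol genes split, with 8 of 25 cholesterol synthesis genes higher and 6 lower, 5 of 14 LXR target genes higher and 4 lower, and 4 of 8 oxysterol genes lower. Abcg1, a cholesterol exporter, rose by 1.52 while the exporter Abca1 fell by 1.73 on the log2 scale. Of 30 activation and adhesion genes, 8 were higher and 5 lower, with the selectin genes Selp at 1.97 and Sele at 2.63 and the adhesion molecule Vcam1 at -2.45. The vehicle libraries stood apart in that list, with medians of -0.65 and 0.65 against their mean, as far as those with TEV (0.62 and 0.37). Of 26 hypoxia and glycolysis genes, 9 were higher and 8 lower, and of 20 NRF2 targets 8 were higher and 5 lower, with Me1 at 3.10 and Nqo1 at 1.92. Of 27 lysosome genes, 6 were higher and 12 lower, with Ctsb at -1.31, and of 28 endocytosis genes 11 were higher and 7 lower, with Ehd4 at 1.81 and the receptor Lrp1 at -5.95. Higher and lower counts were 6 and 12 of 23 immediate early genes, 1 and 7 of 20 unfolded protein response genes, 5 and 4 of 20 p53 targets, 4 and 7 of 12 immune checkpoint genes, and 4 and 3 of 13 drug response genes. They were 2 and 5 of 17 monoamine genes, with the serotonin receptor Htr1b at -5.02, 1 and 6 of 12 mitochondrially encoded transcripts and 1 and 4 of 28 ribosomal protein genes. Of 12 epithelial and mesothelial markers 3 were higher and 5 lower, of 8 lymphatic markers 1 and 5, and of 12 colon tumour markers 5 and 3, with the keratin genes Krt18 at 2.48 and Krt19 at 1.55. Adjusted over the list alone, the counts became 6 and 5 for activation, 9 and 9 for hypoxia, 9 and 5 for NRF2, 7 and 13 for immediate early, 5 and 7 for checkpoint, 0 and 5 for oxysterol, 1 and 7 for mitochondrial and 1 and 3 for ribosomal genes, and stayed the same for the others. Camera adjusted p-values of the 22 lists that were not called ran from 0.0764 to 0.870. The median and mean had opposite signs for cholesterol synthesis (0.02 and -0.02), activation (0.03 and -0.03), interferon receptor (-0.43 and 0.34), endocytosis (0.16 and -0.50) and ribosomal genes (0.01 and -0.08).

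**Figure D2:**
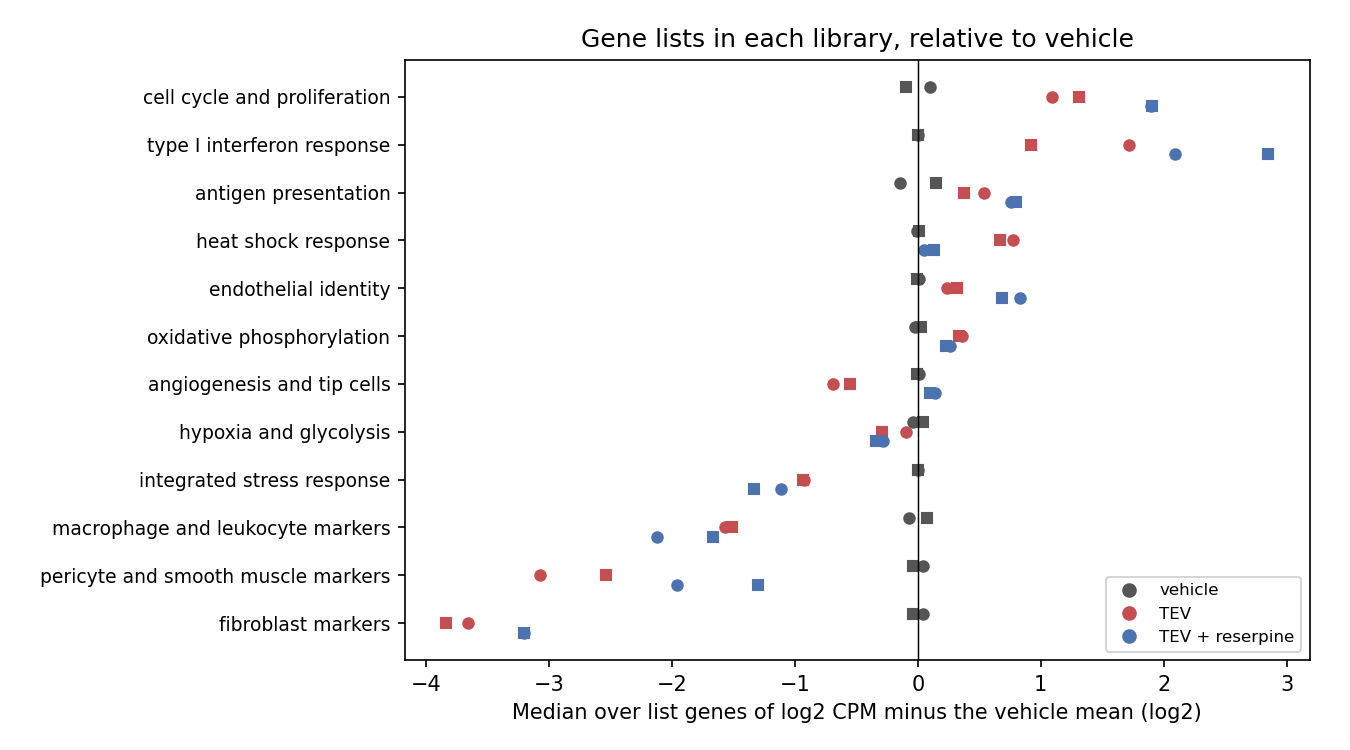
Median over the genes of 12 lists of log2 CPM minus the vehicle mean, one point per library; circles are replicate 1 and squares replicate 2. The cell cycle list lay at 1.10 and 1.31 with TEV and at 1.90 and 1.91 with TEV plus reserpine, and the fibroblast list lay between -3.84 and -3.21 in the 4 libraries that received vesicles.

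The second comparison asked what reserpine pretreatment changes in cells that receive vesicles. With TEV plus reserpine, 11 of 15 heat shock genes and 17 of 26 hypoxia and glycolysis genes were called lower than with TEV. Called higher were 17 of 30 angiogenesis genes, 13 of 25 endothelial identity genes and 20 of 35 cell cycle genes. No list was called by limma camera with an estimated correlation (smallest adjusted p = 0.646 with an estimated correlation). Prss35 fell from 1142 ± 194 to 4.40 ± 0.279 CPM and Hspa1b from 1034 ± 451 to 28.2 ± 3.71 CPM (SD, n = 2 each). Col15a1, a basement membrane collagen, rose from 3.76 ± 1.08 to 240 ± 12.5 CPM, and the Notch ligand Dll4 from 14.3 ± 2.80 to 80.3 ± 7.95 CPM (SD, n = 2 each).

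By edgeR, 2354 genes were higher and 2403 lower, of which 844 and 773 changed at least 2-fold. Scaling by library size alone gave 2857 higher and 1954 lower genes and moved the share of calls that were higher from 49.5% to 59.4%. The counts were 1049 and 1075 without TEV replicate 1, and 1297 and 1284 or 1266 and 1294 without replicate 1 or 2 of TEV plus reserpine. No library of cells with reserpine alone was analysed here, so an effect of reserpine itself is not separated from its effect on the response to vesicles.

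The 10 largest increases by log2 change were in Lrrc55 (6.61, edgeR adjusted p = 3.25e-05), Col15a1 (5.95, 3.71e-05), the pentraxin Ptx3 (4.77, 0.00111), the metalloreductase Steap4 (4.63, 0.00796) and Slitrk5 (4.63, 0.000300). The others were Btnl9 (4.51, 3.25e-05), Aplnr (4.39, 0.000300), Efcc1 (4.29, 0.000671), the potassium channel subunit Kcne3 (3.91, 0.000300) and Mycn (3.66, 0.00259). Aplnr reached 2.24 ± 0.324 CPM (SD, n = 2), far under its vehicle level. The largest decreases were in Gper1 (-9.28, edgeR adjusted p = 0.00144), Prss35 (-8.01, 1.63e-05), the betaine and GABA transporter Slc6a12 (-7.35, 0.00383), the retinoic acid receptor Rarb (-7.05, 0.0138) and the glutamate transporter Slc1a3 (-6.66, 3.71e-05). Also among them were Foxq1 (-6.18, 0.000340), Abcd2 (-6.18, 0.000898), Hspa1b (-5.20, 0.000369) and Gpr149 (-5.06, 0.000340). Tal2 was 258-fold lower, with a counting interval of 88.0 to 1251. The call of Steap4 ended without TEV replicate 1 (adjusted p = 0.0538), and that of Rarb ended without TEV replicate 1 (0.0801) or without replicate 2 of TEV plus reserpine (0.0760). Without replicate 1 of TEV plus reserpine, no counts of Slc6a12 or Rarb remained in that group, so no change is given there. With limma-voom, Gper1 (adjusted p = 0.0598), Slc6a12 (0.0713) and Rarb (0.0956) were not called, nor was Rarb with DESeq2 (0.0960).

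Of 15 heat shock genes, 11 were lower and 1 higher (11 and 2 adjusted over the list alone), with a median of -0.59. Cryab fell by 2.96 and Hsph1 by 2.25 on the log2 scale. Of 26 hypoxia and glycolysis genes, 17 were lower and 3 higher (the same adjusted over the list alone), with a median of -0.51. The glucose transporter Slc2a1 was at -0.93 and the glycolytic enzyme gene Pkm at -0.73, while Ndrg1 rose by 2.37. Camera gave adjusted p = 0.000682 and 0.000234 for these lists (both adjusted p = 0.646 with an estimated correlation). Cell cycle genes were higher for 20 of 35 (25 higher and 1 lower adjusted over the list alone), with a median of 0.51, among them Prc1 (0.80) and Cenpf (1.15). Their camera test gave adjusted p = 1.51e-06 (adjusted p = 0.689 with an estimated correlation).

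Angiogenesis and tip cell genes were higher for 17 of 30 and lower for 5 (20 and 6 adjusted over the list alone), with a median of 0.59. Dll4 rose by 2.48, its fellow Notch ligand Jag1 by 2.50 and the netrin receptor Unc5b by 1.14 on the log2 scale. Of 25 endothelial identity genes, 13 were higher and 5 lower (14 and 6 adjusted over the list alone). The VEGF receptor Kdr rose from 85.3 ± 28.3 to 479 ± 22.6 CPM (SD, n = 2 each) and the angiopoietin receptor Tek by 1.00, whereas Cd34 fell by 1.54 and Ptprb by 1.67 on the log2 scale. By limma camera the lists had adjusted p = 0.000243 and 0.0157 (adjusted p = 0.646 and 0.660 with an estimated correlation). TGF-beta response and matrix genes were higher for 11 of 28 and lower for 4 (13 and 4 adjusted over the list alone), with Lox at 1.28 and Thbs1 at 0.91. Fibroblast markers were higher for 8 of 15 (9 adjusted over the list alone) with a median of 0.75, or 0.86 with genes of an empty group at their bound. Among them the collagen gene Col13a1 rose from 0.958 ± 0.176 to 5.13 ± 1.08 CPM and the fibulin gene Fbln1 from 6.73 ± 0.997 to 13.0 ± 1.60 CPM (SD, n = 2 each). The camera tests had adjusted p = 0.0205 and 0.00672 (adjusted p = 0.689 and 0.646 with an estimated correlation), and the TGF-beta call ended without TEV replicate 1 (adjusted p = 0.0642).

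Of 27 interferon response genes, 8 were higher and none lower (the same adjusted over the list alone), with a median of 0.73 and a camera adjusted p = 0.000243 (adjusted p = 0.784 with an estimated correlation). That list was not called without TEV replicate 2 (adjusted p = 0.107) or with fry (0.166). The response gene Oasl2 was at 1.46 (edgeR adjusted p = 0.0213) and lost its call without replicate 2 of TEV plus reserpine (adjusted p = 0.101). Of 9 receptor and signalling genes, 3 were higher and none lower (the same adjusted over the list alone), with Ifnar1 up by 1.06 (edgeR adjusted p = 0.000812) and Jak1 by 0.40 (0.00955). Antigen presentation genes were higher for 5 of 14 and lower for 2 (7 and 2 adjusted over the list alone), with the peptide transporter Tap1 at 1.74 and H2-T23, of a multigene family, at -1.01. Both lists had a camera adjusted p = 0.0469 (adjusted p = 0.646 and 0.784 with an estimated correlation). The receptor list was not called without TEV replicate 2 (adjusted p = 0.181) or replicate 2 of TEV plus reserpine (0.104). The antigen presentation list was not called without TEV replicate 2 (0.244) or replicate 1 (0.0524) or 2 (0.0677) of TEV plus reserpine, or with fry (0.102).

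The camera test called 3 further lists. Lysosome genes were lower for 12 of 27 and higher for 3 (12 and 4 adjusted over the list alone), with Ctsa at -0.75 and Hexa at 0.60. Drug response genes were higher for 5 of 13 and lower for 1 (the same adjusted over the list alone), with the drug exporter Abcb1a at 1.37 and Ahrr at 0.88. Both had a camera adjusted p = 0.0484 (adjusted p = 0.784 and 0.646 with an estimated correlation). Ribosomal protein genes were higher for 9 of 28 (9 higher and 1 lower adjusted over the list alone), with a median of 0.18 and adjusted p = 0.0105 (adjusted p = 0.813 with an estimated correlation). The lysosome call ended without vehicle replicate 1 (0.0531) or 2 (0.0528), TEV replicate 1 (0.0947) or replicate 2 of TEV plus reserpine (0.142), and with fry (0.123). The drug response call ended without TEV replicate 1 (0.0612) or replicate 2 of TEV plus reserpine (0.0677), and the ribosomal call without replicate 1 of TEV plus reserpine (0.161) or with fry (0.166). Among monoamine genes, Slc18a1, a vesicular monoamine transporter of the kind that reserpine blocks, rose from 1.31 ± 0.146 to 6.11 ± 1.06 CPM (SD, n = 2 each, edgeR adjusted p = 0.00148). Slc18a1 was called lower with TEV than with vehicle, and was not called in TEV plus reserpine against vehicle. The other vesicular monoamine transporter gene, Slc18a2, was named after its values were seen and was also called lower with TEV plus reserpine than with vehicle. Against TEV it fell from 3.26 ± 0.265 to 1.86 ± 0.0448 CPM (SD, n = 2 each, edgeR adjusted p = 0.0369). That call ended with any 1 library left out (adjusted p from 0.0642 without TEV replicate 2 to 0.139 without TEV replicate 1) and with DESeq2 (0.0567), library size alone (0.0507), no filter (0.0570), only the 2 groups fitted (0.0616) or thinned libraries (0.0597). That list had 3 of 17 genes higher and 2 lower (the same adjusted over the list alone) and was not called (camera adjusted p = 0.834), with a median of -0.09 and a mean of 0.20. The inflammatory cyclooxygenase gene Ptgs2 was at -2.33, the chemokine gene Cx3cl1 at 2.67 and the stress gene Nupr1 at -4.29 on the log2 scale. Camera adjusted p-values of the 20 lists that were not called here ran from 0.0544 to 0.949. The median and mean also had opposite signs for the amino acid response (0.03 and -0.06), immediate early (-0.03 and 0.04), oxidative phosphorylation (-0.03 and 0.00), epithelial (-0.09 and 0.17) and colon tumour lists (0.12 and -0.06).

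The last comparison asked how cells with TEV plus reserpine stood against vehicle. With TEV plus reserpine, all 35 cell cycle genes, 24 of 27 interferon response genes, 10 of 14 antigen presentation genes and 17 of 25 endothelial identity genes were called higher than with vehicle. Called lower were 16 of 23 amino acid response genes, 11 of 15 fibroblast markers and 10 of 16 macrophage markers. No list was called by limma camera with an estimated correlation (smallest adjusted p = 0.334 with an estimated correlation). Isg15, an interferon-induced ubiquitin-like protein, rose from 0.900 ± 0.156 to 15.7 ± 2.87 CPM and Esm1 from 28.1 ± 0.107 to 440 ± 8.59 CPM (SD, n = 2 each). Il1rl1, the interleukin 33 receptor, fell from 336 ± 106 to 0.494 ± 0.194 CPM (SD, n = 2 each).

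By edgeR, 2879 genes were higher and 2994 lower, of which 1043 and 1600 changed at least 2-fold. Without vehicle replicate 1 the counts were 1800 and 1772, and without replicate 1 of TEV plus reserpine 1976 genes were lower.

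The 10 largest increases were in Grik1, at least 32.2-fold over the floor, Ppl (log2 change 5.02, edgeR adjusted p = 3.88e-05), Prom1 (4.42, 0.000211), Usp18 (4.41, 0.00194) and Isg15 (4.14, 0.00204). They also held Tnfsf18 (3.99, 0.000206), Esm1 (3.97, 3.55e-06), AU021092 (3.76, 4.7e-05), Pcx (3.74, 0.0364) and the interferon-induced Ifit1 (3.73, 0.00337). Pcx was not called without TEV replicate 2 (adjusted p = 0.0520) or replicate 1 (0.0992) or 2 (0.102) of TEV plus reserpine, nor with DESeq2 (0.208) or only the 2 groups fitted (0.0515). Without vehicle replicate 2 no counts of Pcx remained in vehicle. Tspan11, the xanthine dehydrogenase gene Xdh and Cspg4 had no counts with TEV plus reserpine and were at least 466-fold, 360-fold and 312-fold lower. Gzme, a granzyme, was 1542-fold lower with a counting interval of 276 to 60928, Slc26a7 1099-fold lower (197 to 43421) and the growth factor gene Fgf10 855-fold lower (236 to 7061). Mgp (-9.37, edgeR adjusted p = 4.28e-06), Il1rl1 (-9.32, 1.9e-05), Col1a2 (-9.01, 3.55e-06) and Dkk3 (-8.84, 8.96e-06) completed the list.

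Of 27 interferon response genes, 24 were higher and 1 lower (the same adjusted over the list alone), with a median of 2.64. Bst2 rose by 2.75 and Irf7 by 2.97 on the log2 scale. Of 14 antigen presentation genes, 10 were higher (12 adjusted over the list alone), with Tap1 at 1.18 and H2-K1 at 1.20. Camera gave adjusted p = 7.71e-08 and 5.58e-05 (both adjusted p = 0.495 with an estimated correlation). All 35 cell cycle genes were higher, also when adjusted over the list alone, with a median of 1.95, Rrm2 at 2.13 and Ccnb2 at 2.19. Of 25 endothelial identity genes, 17 were higher and 2 lower (19 and 2 adjusted over the list alone). Emcn rose by 2.39 and Cd34 by 1.81 while Vwf, the von Willebrand factor gene, fell by 2.66 on the log2 scale. Their camera tests gave adjusted p = 6.47e-21 and 1.24e-06 (adjusted p = 0.365 and 0.334 with an estimated correlation).

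Markers of other cell types were again lower than with vehicle, for 11 of 15 fibroblast markers with 1 higher (11 and 2 adjusted over the list alone), 9 of 13 pericyte markers with 1 higher (the same adjusted over the list alone) and 10 of 16 macrophage markers with 1 higher (12 and 1 adjusted over the list alone). The medians were -3.53 (-2.95 with genes of an empty group at their bound), -1.46 and -2.23, with Pdgfra at -5.26 and Pdgfrb at -5.56. By limma camera the lists had adjusted p = 7.49e-05, 0.000483 and 0.00963 (each adjusted p = 0.334 with an estimated correlation). With them, genes of endothelial to mesenchymal transition were lower for 12 of 17 and higher for 3 (the same adjusted over the list alone), with Acta2 at -2.59. TGF-beta response and matrix genes were lower for 15 of 28 and higher for 8 (16 and 10 adjusted over the list alone), with Col1a1 at -6.72 and Bgn at -2.58. The camera tests had adjusted p = 0.00071 and 0.0467 (adjusted p = 0.334 and 0.551 with an estimated correlation), and the TGF-beta call ended without replicate 2 of TEV plus reserpine (0.0622).

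Amino acid response genes were lower than with vehicle for 16 of 23 and higher for 2 (17 and 2 adjusted over the list alone), with Asns at -1.70 and Ddit3, which encodes the stress factor CHOP, at -2.53. Hypoxia and glycolysis genes were lower for 13 of 26 and higher for 3 (14 and 3 adjusted over the list alone), with Vegfa at -4.26, and lysosome genes lower for 12 of 27 and higher for 1 (13 and 1), with Ctsb at -0.93. Camera gave adjusted p = 4.43e-06, 0.00168 and 0.000593 (adjusted p = 0.334, 0.495 and 0.495 with an estimated correlation). Of 20 NRF2 targets, 12 were higher and 2 lower (13 and 2 adjusted over the list alone), with Nqo1 at 0.92 and the glutathione reductase gene Gsr at 1.05. Of 26 oxidative phosphorylation genes, 12 were higher and 1 lower (14 and 1 adjusted over the list alone), with Cox6c at 0.72, whereas 9 of 12 mitochondrially encoded transcripts were lower (the same adjusted over the list alone), with mt-Co3, whose reads can be shared with nuclear copies, at -2.05. Their camera tests gave adjusted p = 0.00683, 0.00187 and 0.00187 (adjusted p = 0.334, 0.495 and 0.495 with an estimated correlation).

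Activation and adhesion genes were higher for 7 of 30 and lower for 4 (the same adjusted over the list alone), with Selp at 2.40 and Sele at 3.38. Ribosomal protein genes were higher for 6 of 28 and lower for 1 (4 and 0 adjusted over the list alone). By limma camera the lists had adjusted p = 0.0106 and 0.0325 (both adjusted p = 0.688 with an estimated correlation). The activation call ended without vehicle replicate 1 (0.621) or with fry (0.186), and the medians of that list in the vehicle libraries stood apart (-0.65 and 0.65). The ribosomal call ended without vehicle replicate 1 (0.176) or replicate 1 of TEV plus reserpine (0.323), or with fry (0.175). The heat shock list, which was higher with TEV alone, had 4 of 15 genes higher and 1 lower (the same adjusted over the list alone) and was not called (camera adjusted p = 0.294). Camera adjusted p-values of the 16 lists that were not called here ran from 0.0518 to 0.867. The median and mean had opposite signs for the angiogenesis (0.08 and -0.20), LXR target (-0.09 and 0.03), endocytosis (0.19 and -0.10) and colon tumour lists (0.13 and -0.01).

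Many genes that were called with TEV against vehicle lay closer to their vehicle level with TEV plus reserpine. Of the 3773 genes higher with TEV, 1551 (41.1%) were lower with TEV plus reserpine than with TEV, and 1085 of these were not called against vehicle. Of the 3703 genes lower with TEV, 1418 (38.3%) were higher with TEV plus reserpine, and 856 of these were not called against vehicle. Prss35, Hspa1b, Dll4 and Kdr were among the genes that moved in opposite directions. Moved back or not, 1980 (52.5%) of the higher genes and 2140 (57.8%) of the lower genes were called on the same side of vehicle with TEV plus reserpine, such as Cd34 and Emcn above it and Vegfa, Asns and Col1a2 below it.

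In all, 2969 genes were called in opposite directions in the first and second comparisons and 363 in the same direction. Independent lists of these sizes would share 603 (higher, then lower) and 580 (lower, then higher) in opposite directions. Groups simulated without any change, compared through the same TEV libraries, shared at most 2 in 20 simulations, which does not measure what the shared libraries add where many genes are called. The covariance of the log2 changes over genes was -0.72 against a simulated mean of -0.08, a difference of -0.64, and the correlation was -0.41 against a simulated -0.48. Each group held 2 libraries, so the shared TEV libraries could not be split into parts of 2, and part of the excess can come from them. The opposite-direction count was 1420 without TEV replicate 1, and 1838 or 1804 without replicate 1 or 2 of TEV plus reserpine, and the covariance was -1.44 without TEV replicate 2. Genes called in the 2 comparisons that share the vehicle libraries moved the same way for 4120 and in opposite ways for 166. Independent lists would share 722 (both higher) and 737 (both lower), and unchanged groups at most 1, with the same limit. The covariance there was 1.90 against a simulated 0.08.

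**Figure D3:**
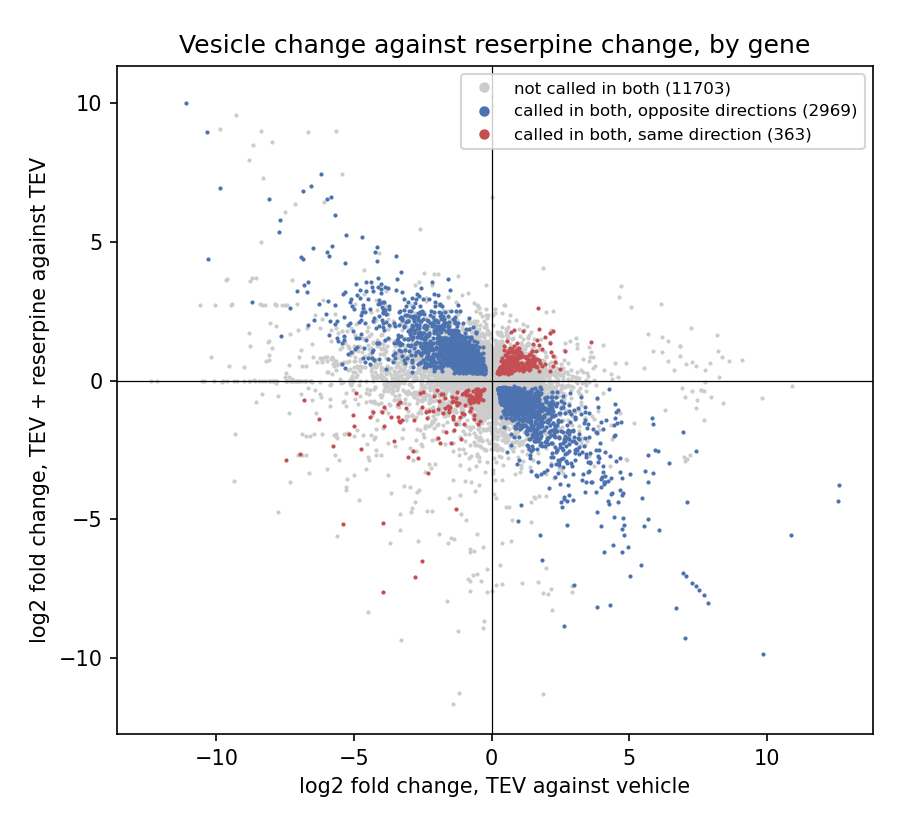
Log2 fold change of each of 15035 genes in TEV against vehicle (horizontal axis) and in TEV plus reserpine against TEV (vertical axis). The 2969 genes called in opposite directions outnumber the 363 called in the same direction, and both comparisons share the TEV libraries.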

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

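The tests of thinned libraries and of the gene set without genes far lower in both vesicle groups were chosen after the results were seen. No gene that was called both in the main test and under an alternative changed sign between them. Other tests, scalings, filters and gene sets kept 77.3% to 99.0% of calls for TEV against vehicle, 86.3% to 98.2% for TEV plus reserpine against TEV and 79.7% to 99.8% for TEV plus reserpine against vehicle. With 1 library left out, and the lone library assumed to vary like the others, 69.3% to 94.9%, 43.7% to 80.7% and 58.3% to 94.9% of calls stayed. Higher and lower counts with a library left out ran from 2668 to 3779 and 2713 to 3713 for TEV against vehicle, 1049 to 2177 and 1075 to 2138 for TEV plus reserpine against TEV, and 1800 to 2977 and 1772 to 2980 for TEV plus reserpine against vehicle. The opposite-direction count ran from 1420 to 2883, the covariance from -1.44 to -0.77, and called lists from 10 to 13, 10 to 13 and 16 to 19; fewer libraries leave fewer degrees of freedom, and the cause was not tested further. A minimum log2 change of 1 left 1346 and 2106, 844 and 773, and 1043 and 1600 genes and 980 in opposite directions, by construction; it was not applied to the covariance or to single genes. The covariance was -1.20 with no filter and -0.46 with a filter of 5 CPM, which change the genes used. With an estimated correlation 0 lists were called in each comparison, with smallest adjusted p-values by limma camera of 0.462, 0.646 and 0.334, and fry called 22, 16 and 25. In TEV against vehicle, fibroblast markers (estimated correlation 0.0350) and cell cycle genes (0.580) had the same camera adjusted p = 0.462. Immediate early genes, estimated at -0.00668 and so below the preset 0.01, went from a camera adjusted p of 0.149 to 0.462. The size of the estimated correlation alone therefore does not account for the higher p-values, and the cause was not tested further.

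Deviations of libraries with the same title number from their group means correlated at 0.02, 0.02 and -0.04 over all genes tested. This gave no sign of pairing by title number but cannot exclude it, since noise of genes with few counts enters these values. Pairing by description number was not checked in this way. With the title number as a replicate block, calls were 3438 and 3426, 1910 and 1930, and 2503 and 2591, with 2465 in opposite directions and 11, 16 and 18 lists. With the description number as a replicate block, which left 1 residual degree of freedom, calls were 2173 and 2395, 1797 and 1741, and 1256 and 1446, with 1959 in opposite directions. The call of Ch25h in TEV plus reserpine against vehicle ended with either replicate block (edgeR adjusted p = 0.0646 and 0.252). Without genes far lower in both vesicle groups, 2926 genes moved in opposite directions, and after thinning 2882 did. Of 164 named values, 9 lost their call under at least 1 alternative, all with the same sign, in 36 cases over all alternatives. The call of Slc18a2 in TEV plus reserpine against TEV ended with either replicate block (edgeR adjusted p = 0.0671 and 0.116). Detection of changes of 1 on the log2 scale was incomplete at this depth and group size.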

Other observations

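All tests in this part, and the lists of arterial, venous, junction and further marker genes, were chosen only after the results were seen.

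Of 20 genes of arterial endothelium, picked after their values were seen, 16 were called lower and 1 higher with TEV than with vehicle (median log2 change -1.23). With TEV plus reserpine against TEV, 14 were higher and none lower (median 1.15), and against vehicle 3 were higher and 7 lower. No test of these lists is given, since the genes were picked for what they showed. The Notch ligand gene Dll4 was at 90.0 and 85.3 CPM with vehicle, 12.3 and 16.3 with TEV and 85.9 and 74.7 with TEV plus reserpine. The Notch target Hey1 was at 7.62 and 6.89, 1.19 and 1.15, and 3.48 and 3.53 CPM, and Efnb2, the ephrin-B2 gene, at 175 and 171, 67.8 and 86.1, and 168 and 195 CPM. Of 16 venous and capillary genes, 6 were higher and 6 lower with TEV, and 7 higher and 4 lower with reserpine added.

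Of 16 endothelial junction genes, 8 were higher and 4 lower with TEV than with vehicle, 5 higher and 2 lower with reserpine added, and 7 higher and 2 lower in TEV plus reserpine against vehicle. The tight junction gene Cldn5 was at 221 and 220 CPM with vehicle, 20.2 and 37.3 with TEV and 182 and 148 with TEV plus reserpine. The gap junction gene Gja1 was at 463 and 483, 94.5 and 108, and 268 and 278 CPM. Edn1, the endothelin-1 gene, was at 26.6 and 27.6, 193 and 265, and 247 and 251 CPM. These genes too were chosen after their values were seen.

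Markers of other lung cell types were lower in both vesicle groups than in vehicle. A smaller share of other cells could give this. The weakest of 6 medians of further markers was -1.38 (8 macrophage genes, TEV plus reserpine against vehicle). Its interval over resampled genes was -4.88 to 0.30, which leaves the explanation open. Loss of a mesenchymal programme in the endothelial cells is unlikely as the whole cause. The macrophage list fixed beforehand had medians of -2.20 (interval -3.16 to -0.74) and -2.23 (-3.47 to -0.88) against vehicle. Macrophage genes outside that list gave weaker evidence, with -1.69 (-2.74 to -0.16) for TEV and the interval above, which includes 0, for TEV plus reserpine. Further mesothelial genes left it open with TEV (-4.06, interval -5.95 to 1.53) but were lower with TEV plus reserpine (-2.39, -6.40 to -0.12). Depth is unlikely, as the fibroblast median stayed at -4.26 after thinning. Separate cell preparations and an effect of the vesicles themselves could not be told apart here.

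Of the genes called higher or lower with TEV, 41.1% and 38.3% were called in the opposite direction with reserpine added, and 52.5% and 57.8% were still called on the same side of vehicle. With different TEV libraries in the 2 comparisons, which then shared none, the covariance stayed at -0.619 in the weaker of 2 splits (interval over resampled genes -0.705 to -0.531), so chance spread of shared libraries is unlikely as the whole cause. In these splits 1641 and 2192 genes moved in opposite directions against 476 and 849 for independent lists, although a deviation of TEV replicate 1 alone entered only 1 comparison. In the same direction moved 155 and 410 against 476 and 849. The splits remove the spread of single TEV libraries, but not a deviation common to both. Such a deviation enters the 2 comparisons with opposite signs, and by itself gives more opposite and fewer same-direction calls than independent lists. These counts therefore do not decide whether the reserpine effect was unrelated to that of the vesicles. Separate cultures remain possible, and no library with reserpine alone was used here.

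Cell cycle genes were higher in both vesicle groups. Dilution of endothelial RNA by other cells in the vehicle libraries could give this and stays open, as the comparisons differed. With TEV the cell cycle median exceeded that of endothelial identity genes by 0.91 (interval over resampled genes 0.44 to 1.65). That was less than the SD of the endothelial identity genes (1.66), which moved both ways. With TEV plus reserpine the difference was 1.24 (0.77 to 1.38), more than the SD (0.99). Dilution was to count as unlikely only with a difference above the SD in both comparisons, so these values do not decide it. The intervals cover the choice of genes and not the spread between libraries. Depth is unlikely, as 34 of 35 genes stayed higher in both comparisons after thinning. Different culture states of the groups could not be tested.

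The Y-linked genes Ddx3y (25.5 to 42.9 CPM), Eif2s3y (19.6 to 27.1), Uty (11.3 to 21.5) and Kdm5d (16.8 to 21.8) were present in all 6 libraries, whereas the labels give the sex as female. The vehicle libraries differed in Cxcl1 (0.859 and 52.2 CPM), Csf3 (0.999 and 19.5), Ccl2 (77.6 and 411) and Lif (53.8 and 185). Of 4037 genes not called with TEV and within 0.25 of no log2 change, 100 changed at least 2-fold with TEV plus reserpine against TEV and were called the same way against vehicle, 48 higher and 52 lower. In both vesicle groups 483 genes were lower than with vehicle by at least 3 on the log2 scale, and they held 2.45% and 2.44% of the counts of the vehicle libraries.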
